A study of Mus musculus with 12 samples.

How the data were processed

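The study measured gene expression by sequencing of poly-A RNA in primary B lymphocytes sorted from 3 wild type and 3 Tmem173-/- mice. Tmem173 encodes STING, the receptor for cyclic dinucleotides. Cells were seeded in 96-well plates and either left as controls or treated for 12 hours with 3'3'-cGAMP, a cyclic dinucleotide of bacteria that binds STING. Libraries were prepared with a NEBNext Ultra kit. The 12 libraries form 4 groups of 3, namely wild type control, wild type cGAMP, Tmem173-/- control and Tmem173-/- cGAMP. The labels do not state whether control and cGAMP libraries with the same number come from the same mouse. With 3 mice per genotype and 3 libraries in each group, the libraries of a genotype cannot all come from different mice. The primary fit nevertheless treated libraries as independent, and a fit with the number as a block was run as an alternative.

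The authors deposited a count for each gene and library, and, as a second unit, an FPKM value. Per the submitters' processing notes, reads were trimmed with fastp, aligned with STAR and assigned to genes with featureCounts. The notes name the mouse builds GRCm38 and mm10, and give neither versions nor settings. The annotation release and the strandedness of the libraries are not stated. The deposited count values were whole numbers, and the count table with gene names held the same values as the one without. The ratio of deposited count to FPKM, scaled by the column total, was constant across libraries within a relative spread of 9.8e-15, so both describe the same assignments. Of 54532 gene identifiers in the table, 54495 were found in GENCODE mouse release 21, and 53585 of these had the same start and end there. Coordinates are those given with the deposited counts. Where 103 identifiers shared a name with a more abundant identifier, the plain name was kept for the more abundant one.

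Total counts per library were 28227392, 28160922 and 30971957 for wild type control replicates 1 to 3 and 26835362, 28443085 and 27704086 for wild type cGAMP. They were 31417833, 29402433 and 26490593 for Tmem173-/- control and 26852302, 30502249 and 28941536 for Tmem173-/- cGAMP. A count of 26792 genes had at least 1 count in some library. Where all libraries of a group held 0 counts, folds were computed against a floor of 3 counts over the group. They are lower bounds only for the counts observed in the other group, whose own counting error they leave out. Floors and counting intervals cover counting error at most, since PCR reads without molecular identifiers are not independent molecules.

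Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group, which left 14473 tested genes, and libraries were scaled by TMM. Dispersions and quasi-likelihood fits were robust, with a mean for each of the 4 groups. Quasi-likelihood F tests were two-sided, and p values were adjusted by Benjamini-Hochberg within each of 5 contrasts, with a threshold of 0.05. The contrasts were wild type cGAMP against wild type control, Tmem173-/- cGAMP against Tmem173-/- control, the difference between these responses, Tmem173-/- control against wild type control, and Tmem173-/- cGAMP against wild type cGAMP. The standard error (SE) of a log2 fold change was its size over the square root of F. Expression levels are CPM, which scale each count by the library total after TMM, given as mean ± SD with n = 3 libraries. Intervals for single genes in the Tmem173-/- response are 95% intervals from limma-voom (limma 3.58.1).

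A set of 16 pathway lists and 7 lists of markers of other cell types was fixed, together with the contrasts, tests, alternatives and the rule for named genes, before the data were examined. The pathway lists were interferon-stimulated genes, cytokines and chemokines, regulatory B cell genes, STING pathway components, NF-kB pathway and targets, B cell activation and costimulation, MHC class I presentation, MHC class II presentation, p53 targets and apoptosis, unfolded protein response, cell cycle, plasma cell differentiation, B cell identity and receptor signalling, migration receptors, glycolysis and cholesterol synthesis. The cell type lists were T cell, NK cell, monocyte and macrophage, neutrophil, dendritic cell, erythroid, and platelet and megakaryocyte. Lists were tested with limma camera on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 23 lists within each contrast. Camera with an estimated correlation and the rotation test fry served as alternatives. Single values per library were compared by exact two-sided permutation tests, for which 3 against 3 libraries give p = 0.1 at the smallest.

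Named genes were Tmem173 and, for wild type cGAMP against control, the 10 higher and 10 lower genes with the largest fitted change among those past the threshold. These had to have a mean of at least 5 CPM in the higher group, all 3 libraries of that group above all 3 of the other, and a symbol that is not a predicted or clone name nor an immunoglobulin or T cell receptor segment. For the other contrasts the number was 5 in each direction, and for the difference of responses the separation of libraries was not required. In each list, the 4 called members with the largest change in wild type cells were named, together with all members of the regulatory B cell list and any list member behind a count of 5 or fewer.

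The pipeline was tested on simulated data in which 66 or 67 genes at each fold were changed in the cGAMP libraries of 1 genotype. In the wild type contrast it recovered 52.2% of genes changed 1.5-fold, 70.2% of those changed 2-fold and 81.8% of those changed 4-fold, with 10 false calls. In the Tmem173-/- contrast the shares were 43.3%, 73.1% and 90.9%, with 11 false calls. For the difference of responses they were 26.9%, 56.7% and 78.8% with 11 false calls when wild type libraries were changed, and 13.4%, 61.2% and 84.9% with 12 false calls when Tmem173-/- libraries were changed. Among genes at 5 CPM or more, the Tmem173-/- contrast recovered 63.6% at 1.5-fold and 100% at 2-fold, and the wild type contrast 77.8% and 95.6%. Contrasts without a simulated change gave 0 or 1 false calls. A shifted set of genes was called by camera with the preset (p = 1.95e-25) and with the estimated correlation (p = 3.32e-06). Only a small part of the 14473 genes was changed, while 47.8% were called in the wild type contrast of the data. The recovered shares need not hold there. Genes were simulated independently of each other and without a mouse effect. In the data, the estimated correlation of the interferon-stimulated list was 0.714. The simulation therefore does not test the preset correlation on lists whose genes move together.

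The alternatives tried were median-of-ratios scaling and library totals alone, no filter on low counts and a filter at 1 CPM in 6 libraries, DESeq2 1.42.0, limma-voom, and limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) for genes at an FPKM of 1 or more in 3 libraries and on log2(FPKM + 1) for all genes above 0. Others were a fit of the contrast's groups alone, the replicate number as a block, glmTreat against a log2 fold change of 1, and leaving out each library in turn. Chosen after seeing the data were a fit without both wild type replicate 1 libraries and the interferon list without wild type control replicate 3. All 12 libraries were used, and no library was left out of the values reported as primary.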

Results

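RNA from B lymphocytes of wild type mice and of mice labelled Tmem173-/- was compared with and without 12 hours of 3'3'-cGAMP, an agonist of the receptor STING. There were 3 libraries in each of 4 groups, with 26490593 to 31417833 assigned counts per library and 18556 to 19727 genes detected in each. On a principal component analysis of log2 CPM, the first component held 53.9% of the variance and the second 8.80%. Mitochondrial transcripts made up 1.60% to 1.91% of counts in wild type controls, 1.19% to 1.32% after cGAMP in wild type cells, and 1.76% to 2.26% in the Tmem173-/- libraries.

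Tmem173 (ENSMUSG00000024349, GRCm38 chromosome 18, 35733678 to 35740554) was measured first, as the gene named in the genotype. Its RNA was at 91.2, 102 and 92.7 CPM in wild type controls and at 80.2, 94.7 and 103 CPM in libraries labelled Tmem173-/- control. After cGAMP it was at 44.7, 49.2 and 48.0 CPM in wild type and at 82.9, 101 and 95.9 CPM in Tmem173-/-. The transcript was therefore not lower in the libraries labelled Tmem173-/- (log2 fold change -0.04 between controls, edgeR adjusted p = 0.935, n = 3 per group), and the RNA alone does not show the genotype of these cells. The sign of this small difference flips with library totals alone, where it was 0.01. Every direction between genotypes below rests on the labels. In wild type cells cGAMP lowered Tmem173 RNA from 95.3 ± 5.95 to 47.3 ± 2.37 CPM (log2 fold change -1.01, SE 0.10, edgeR adjusted p = 8.07e-07), and in Tmem173-/- cells the levels were 92.7 ± 11.5 and 93.3 ± 9.45 CPM (SD, n = 3).

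The comparison of wild type cGAMP with wild type control asked which transcripts a STING agonist changes in B cells. Camera with a preset correlation called the lists of interferon-stimulated genes, cytokines and chemokines, NF-kB pathway and targets, MHC class I presentation and cell cycle higher after cGAMP. It called the lists of MHC class II presentation, B cell identity and receptor signalling, and migration receptors lower. None of these calls held with an estimated correlation. The rotation test fry, which asks whether a list's genes move on balance in 1 direction and does not compare them with other genes, called 12 of the 16 pathway lists, these 8 among them. Cxcl10 (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889), a chemokine that attracts T cells, rose from 0.589 ± 0.702 to 87.0 ± 5.63 CPM (SD, n = 3), a log2 fold change of 7.19 (SE 0.50). Ifih1 (chromosome 2, 62595798 to 62646255), the cytosolic RNA sensor MDA5, rose from 14.2 ± 4.70 to 458 ± 6.19 CPM. Rnf150 (ENSMUSG00000047747, chromosome 8, 82863356 to 83091268), a RING finger protein gene, fell from 13.2 ± 2.09 to 0.436 ± 0.0943 CPM. With edgeR, 3238 genes were higher and 3683 lower at an adjusted p under 0.05, which is 47.8% of the 14473 tested, and of these 978 were at least 2-fold higher and 1004 at least 2-fold lower. Without both wild type replicate 1 libraries, which held more neutrophil, T cell and NK cell transcripts (given with the cell type lists), 2487 were higher and 3056 lower.

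Among the 10 largest rises, Aire, the transcriptional regulator of self-antigen expression in the thymus, rose by a log2 fold change of 7.18 (SE 0.50) from 0.117 to 17.8 CPM. The type I interferon genes Ifna4 and Ifna1 rose by 6.77 (SE 0.54) and 6.64 (SE 0.67), with 4 and 5 counts over the 3 control libraries against 478 and 539 after cGAMP. The interferon-inducible p200 family members Ifi204 and Ifi207 rose by 5.80 and 5.44. Ifna1 and Ifna4, and Ifi204 and Ifi207, are members of the same gene families. Reads may have been shared within each pair, which was not checked, so which member rose is uncertain. Tex15, a gene of male meiosis, rose by 5.98, the kinase gene Pak6 by 5.94, and Acod1, whose enzyme makes itaconate, by 5.43. EdgeR adjusted p values of these 10 genes, Cxcl10 and Ifih1 included, lay between 9.47e-10 and 3.66e-06. Ifnb1, the gene of interferon beta, was below the filter and not tested. It had 24 counts over the wild type cGAMP libraries and 0 over the controls, at least 8.42-fold higher.

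Among the 10 largest falls after Rnf150, Crisp3, a cysteine-rich secretory protein, fell by 4.66 on the log2 scale (SE 0.48) and the chemokine receptor gene Ccr1 fell by 3.91 (SE 0.19). Pglyrp1, a peptidoglycan recognition protein, fell by 3.19, and Nfam1, an activating receptor with an ITAM, fell by 3.10. Sema5a, a semaphorin, fell by 3.03, Anxa1, encoding annexin A1, fell by 2.82, and Bmf, a pro-apoptotic BH3-only gene, fell by 2.82. Adgre1, the gene of the macrophage marker F4/80, fell by 2.80 from 30.8 ± 7.48 to 4.41 ± 0.793 CPM, and Wnt1, a secreted signalling protein, fell by 2.72. EdgeR adjusted p values of the 10 lay between 4.78e-11 and 5.7e-05.

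**Figure D1:**
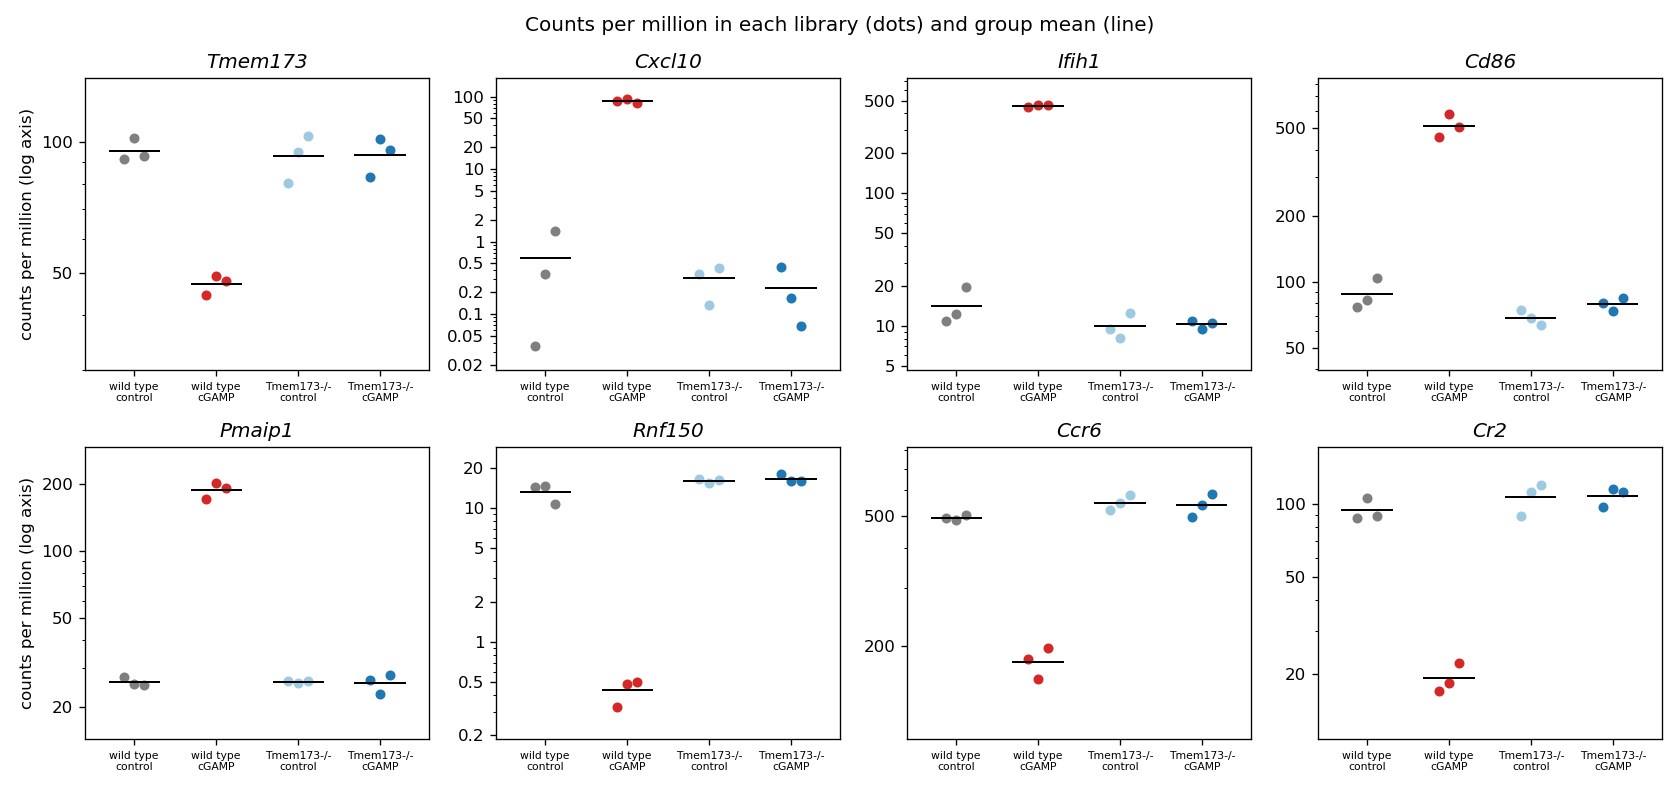
CPM (log axes) of 8 genes in each library, with dots for libraries and lines for group means (n = 3). Tmem173 stands at 44.7 to 49.2 CPM in the wild type cGAMP libraries and at 80.2 to 103 CPM in the other 9 libraries.

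Of 35 interferon-stimulated genes, 34 rose and 0 fell in wild type cells, and all 35 passed when adjusted over the list alone. Ifit1, an RNA-binding antiviral protein, rose by 4.96, Rsad2, encoding viperin, by 4.51 and Oasl1, an oligoadenylate synthetase-like gene, by 4.45. Gbp2, a guanylate-binding protein gene, did not pass (log2 fold change 0.52, edgeR adjusted p = 0.076). The list median was 2.72 (camera adjusted p = 3.06e-17, adjusted p = 0.328 with an estimated correlation). Wild type control replicate 3 stood above the other controls on this list. The mean log2 CPM over the list was 4.09, 4.73 and 5.56 in the wild type controls and 7.63, 7.81 and 7.56 after cGAMP, a difference of 2.87 in the group means (exact permutation p = 0.1, the smallest possible). Without control replicate 3 the list median was 3.09, with 34 of 35 members higher.

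**Figure D2:**
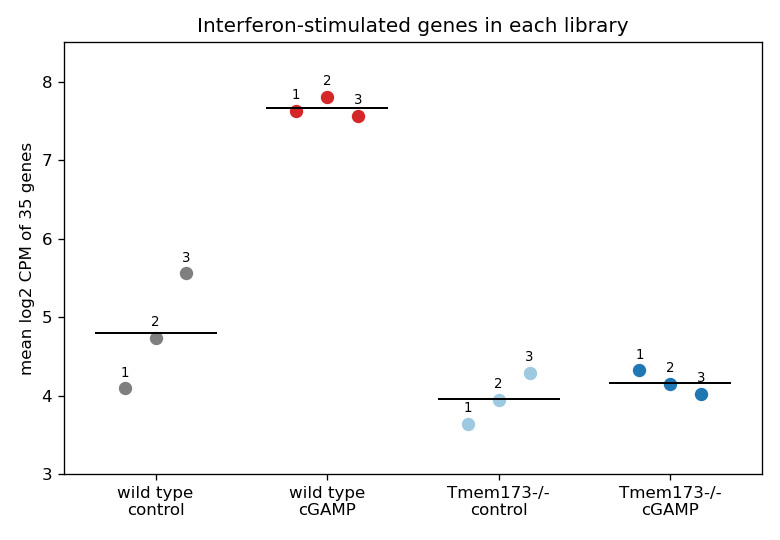
Mean log2 CPM over 35 interferon-stimulated genes in each library (dots), with group means (lines). Wild type cGAMP libraries lie at 7.56 to 7.81, wild type controls at 4.09 to 5.56 and the Tmem173-/- libraries at 3.64 to 4.32.

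Of 16 tested cytokine and chemokine genes, 11 rose, 1 fell and 4 did not pass, and 14 passed when adjusted over the list alone. Besides Cxcl10, Ccl5, a chemokine for T cells, rose by 4.19, the inflammatory cytokine Il6 by 3.81 and lymphotoxin alpha (Lta) by 3.55. Ltb, the gene of lymphotoxin beta, fell by 0.83. The list median was 1.48 (camera adjusted p = 4.5e-05, adjusted p = 0.301 with an estimated correlation). Of 23 NF-kB pathway genes and targets, 13 rose, 4 fell and 6 did not pass, and 17 passed when adjusted over the list alone. Ier3 rose by 2.72, Gadd45b by 1.94, Nfkbiz by 1.13 and Traf1 by 1.04, all of them known targets of NF-kB, while Rela, Bcl2a1b, Cd83 and Tnip1 fell. The median was 0.31 (camera adjusted p = 0.00591, adjusted p = 0.328 with an estimated correlation).

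Of 20 genes of B cell activation and costimulation, 9 rose, 6 fell and 5 did not pass, and 16 passed when adjusted over the list alone. The CD28 ligand genes Cd80 and Cd86 rose by 2.92 and 2.55, with Cd86 going from 87.9 ± 14.3 to 515 ± 63.5 CPM, and the interleukin 2 receptor alpha chain gene Il2ra rose by 1.47. Egr2, an immediate early transcription factor downstream of the antigen receptor, fell by 1.84. The list as a whole was not called by camera (median 0.21, camera adjusted p = 0.377) and was called higher by fry (fry adjusted p = 0.00108). Of 18 genes of MHC class I presentation, 14 rose, 0 fell and 4 did not pass. Adjusted over the list alone 15 passed, 14 higher and 1 lower. Nlrc5, the transactivator of class I genes, rose by 1.51, and H2-Q4, H2-Q6 and H2-Q7 rose by 1.58, 1.46 and 1.17, with reads possibly shared among these paralogs. The median was 0.62 (camera adjusted p = 2.3e-05, adjusted p = 0.328 with an estimated correlation). Of 14 genes of MHC class II presentation, 0 rose, 13 fell and Ifi30 did not pass, with 13 past the threshold when adjusted over the list alone. March1, a ubiquitin ligase that removes class II molecules from the surface, fell by 2.23, H2-Oa by 1.72, H2-DMa by 1.71 and the class II beta chain gene H2-Eb2 by 1.63. The median was -1.35 (camera adjusted p = 6.33e-07, adjusted p = 0.328 with an estimated correlation).

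Of 25 genes of B cell identity and receptor signalling, 20 fell, 2 rose and 3 did not pass, and 22 passed when adjusted over the list alone. The complement receptor gene Cr2 fell by 2.29, the low-affinity IgE receptor gene Fcer2a by 2.10, Vpreb3 by 1.88 and the IgM receptor gene Fcmr by 1.64. The median was -0.76 (camera adjusted p = 2.99e-08, adjusted p = 0.328 with an estimated correlation). Of 19 migration receptor genes, 3 rose, 12 fell and 4 did not pass, and 15 passed when adjusted over the list alone. The gut-homing integrin chain gene Itgb7 fell by 2.07, the chemokine receptor gene Ccr6 by 1.47, the sphingosine 1-phosphate receptor gene S1pr4 by 1.40 and the oxysterol receptor gene Gpr183 by 1.21, while Ccr7, Ccr9 and Itgb1 rose. The median was -0.66 (camera adjusted p = 0.00271, adjusted p = 0.328 with an estimated correlation). Of 25 cell cycle genes, 17 rose, Cenpa fell and 7 did not pass, and 20 passed when adjusted over the list alone. Ccnd2, encoding cyclin D2, rose by 2.50, the checkpoint kinase gene Bub1 by 2.29, Cdk1 by 1.88 and the ribonucleotide reductase gene Rrm2 by 1.87. The median was 0.91 (camera adjusted p = 6.69e-06, adjusted p = 0.484 with an estimated correlation).

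The regulatory B cell list held genes used to define B cells that restrain other immune cells. Of 18 tested members, 5 rose, 8 fell and 5 did not pass, and 14 passed when adjusted over the list alone. Among those that rose, the inhibitory cytokine gene Il10 went from 0.259 ± 0.266 to 3.04 ± 0.788 CPM (log2 fold change 3.53, SE 0.59, edgeR adjusted p = 0.000129, n = 3). The inhibitory receptor genes Tigit and Lag3 rose by 4.12 and 3.21, Cd274, encoding PD-L1, by 1.06, and Ebi3, a chain of interleukins 27 and 35, by 0.65. Those that fell were Havcr1 (TIM-1) by 1.53, Cd24a by 1.52, Cd5 by 1.5, Cd9 by 1.27, the lipid antigen presenting gene Cd1d1 by 0.84, Tgfb1 by 0.75, the plasma cell regulator Prdm1 by 0.66 and the ectonucleotidase gene Entpd1 by 0.51. Not past the threshold were Il12a (0.01), Pdcd1lg2 (-0.25), Nt5e (-0.42), Ctla4 (-0.37) and Fasl (-2.49). The list was not called by camera (camera adjusted p = 0.397) and was called lower by fry (fry adjusted p = 0.00422), and its median of -0.47 and mean of 0.03 differed in sign. Ebi3 did not pass without wild type control replicate 1 (edgeR adjusted p = 0.0709) or wild type cGAMP replicate 3 (edgeR adjusted p = 0.0514), Entpd1 did not pass without wild type control replicate 3 (edgeR adjusted p = 0.0611), and Prdm1 did not pass on log2(FPKM + 1) (limma-trend adjusted p = 0.0619). Fasl passed with the replicate number as a block (edgeR adjusted p = 0.0302), with limma-voom (limma-voom adjusted p = 0.0366) and without the filter on low counts (edgeR adjusted p = 0.044). It also passed without wild type cGAMP replicate 1 (edgeR adjusted p = 0.0149), the only wild type cGAMP library in which it was counted (5 counts, against 30 over the controls), and without both wild type replicate 1 libraries (edgeR adjusted p = 0.0317). With the cGAMP library of replicate 1 left out, the other cGAMP libraries held 0 counts of Fasl, at least 6.43-fold lower than the controls. Over all alternatives the adjusted p ranged from 0.00258 to 1 for Ebi3, 0.00534 to 1 for Entpd1, 0.00755 to 1 for Prdm1 and 0.0149 to 0.611 for Fasl.

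The remaining pathway lists changed in both directions and none was called as a whole by camera, while fry called STING pathway components (fry adjusted p = 0.00261) and p53 targets and apoptosis (fry adjusted p = 0.000342) higher. Of 18 STING pathway components, 7 rose, 5 fell and 6 did not pass, with 12 past the threshold when adjusted over the list alone (median 0.15, camera adjusted p = 0.538). Besides Ifi204 and Tmem173, the cGAMP synthase gene Mb21d1 rose by 1.57 and the ectonucleotidase gene Enpp1 fell by 1.39. Of 20 p53 targets and apoptosis genes, 9 rose, 6 fell and 5 did not pass, with 15 when adjusted over the list alone (median 0.26, camera adjusted p = 0.377). The pro-apoptotic BH3-only genes Pmaip1 (NOXA) and Bbc3 (PUMA) rose by 2.85 and 2.32 and the cell cycle inhibitor gene Cdkn1a by 1.45, while Gadd45a fell by 2.13. Of 22 genes of the unfolded protein response, 7 rose, 6 fell and 9 did not pass, with 13 when adjusted over the list alone (median 0.11, camera adjusted p = 0.654). The stress transcription factor genes Atf3 and Atf4 rose by 4.30 and 0.74 and the phosphatase subunit gene Ppp1r15a by 1.11, while Sdf2l1 fell by 0.62.

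Of 15 plasma cell differentiation genes, 2 rose, 4 fell and 9 did not pass, with 6 when adjusted over the list alone (median -0.26, camera adjusted p = 0.654). Sdc1, encoding the plasma cell marker CD138, fell by 1.87 and Mzb1 by 0.75, while the amino acid transporter genes Slc3a2 and Slc7a5 rose by 1.15 and 0.99. Of 17 glycolysis genes, 3 rose, 5 fell and 9 did not pass, with 8 when adjusted over the list alone (median 0.10, camera adjusted p = 0.956). Hexokinase 2 (Hk2) rose by 1.28, while Pdk1, Eno1 and Hk1 fell by 0.59, 0.55 and 0.49. Of 19 cholesterol synthesis genes, 4 rose, 6 fell and 9 did not pass, with 11 when adjusted over the list alone (median -0.01, which became 0.01 with median-of-ratios scaling and 0.06 with library totals, camera adjusted p = 0.722). Fdps rose by 1.01, while Stard4, Mvk and Srebf2 fell by 0.54, 0.53 and 0.50.

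**Figure D3:**
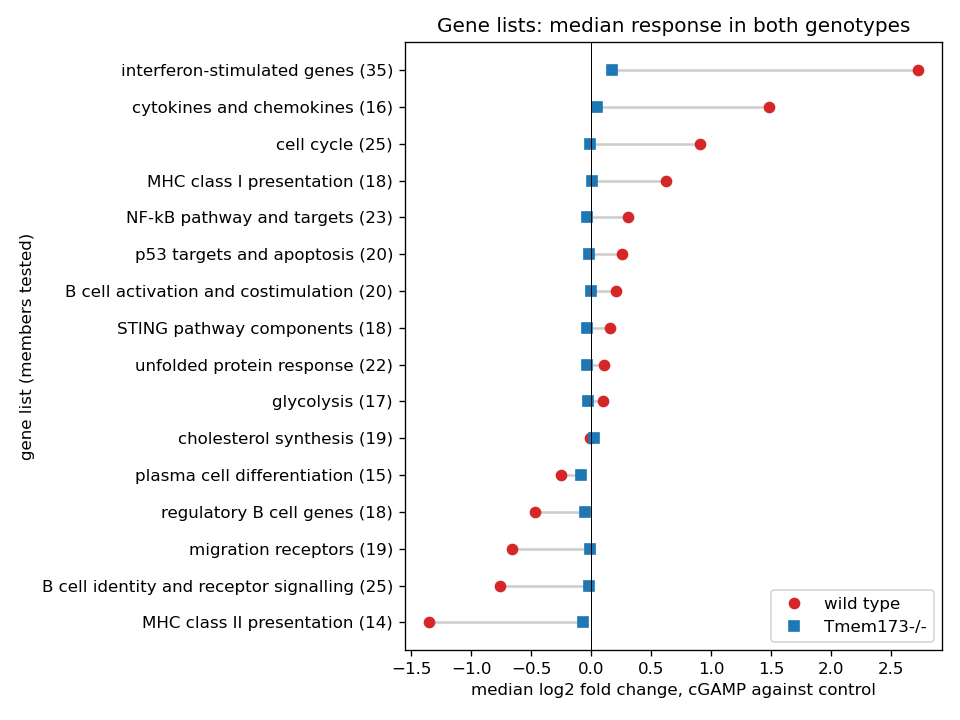
Median log2 fold change of each of 16 pathway lists after cGAMP in wild type and in Tmem173-/- cells. The interferon-stimulated genes have a median of 2.72 in wild type and 0.17 in Tmem173-/- cells, and the MHC class II genes -1.35 and -0.07.

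Of the markers of other cell types, none of the 7 lists was called by camera in this comparison, while fry called monocyte and macrophage markers lower (fry adjusted p = 0.00422) and dendritic cell markers higher (fry adjusted p = 0.00835). Of 9 tested T cell markers 8 did not pass and Lck, a kinase at 209 ± 16.1 CPM in wild type controls, fell by 0.74 (list camera adjusted p = 0.888). Of 6 monocyte and macrophage markers, Adgre1 fell by 2.80 and Ms4a7 fell from 0.177 ± 0.0615 CPM to 0 in each cGAMP library (0.48), and of 5 dendritic cell markers, Zbtb46 and Flt3 rose, by 1.69 and 1.09 (0.377). None of 4 NK cell (0.425), 2 neutrophil (0.834), 3 erythroid (0.834) or 4 platelet and megakaryocyte markers (0.72) passed, where the values in brackets are camera adjusted p values. Wild type replicate 1 held more counts of some neutrophil, T cell and NK cell genes than the other libraries, genes chosen after their values were seen. The neutrophil gene Ngp had 36 counts in its control and 122 in its cGAMP library, Cd3e of T cells 25 and 84, and Cd8a 46 and 98, against at most 9 counts of each in any of the other 10 libraries. Of the NK cell genes below the filter, Gzma had 9 and 23 counts there and 0 in each of the other libraries. Ncr1 had 2 and 18, Klre1 0 and 14, Klra8 1 and 8 and Eomes 10 and 9, against at most 3 of each elsewhere, while Klrb1c had 0 and 0 there and up to 10 elsewhere. Itgam of myeloid cells had 3 and 4 there and up to 10 elsewhere.

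The comparison of Tmem173-/- cGAMP with Tmem173-/- control asked whether B cells labelled as lacking STING respond to the same agonist. No gene passed the threshold with edgeR (0 higher, 0 lower), while 203 genes had an unadjusted p under 0.05 where chance gives 723.7. A count below chance points to conservative p values, so it is not evidence that a response is absent. DESeq2, limma-voom and edgeR with the replicate number as a block gave 0 in each direction as well. Cxcl10 was at 0.311 ± 0.158 and 0.227 ± 0.197 CPM in control and cGAMP (95% interval of the log2 fold change -2.76 to 1.5), Ifih1 at 10.02 ± 2.21 and 10.3 ± 0.663 CPM (-0.37 to 0.50), Cd86 at 68.6 ± 5.52 and 79.2 ± 5.07 CPM, and Rnf150 at 16.0 ± 0.487 and 16.5 ± 1.15 CPM (-0.21 to 0.29; SD, n = 3). These intervals exclude the wild type changes of Cxcl10, Ifih1 and Rnf150. Genes that rose in wild type cells had a median log2 fold change of 0.65 there and 0.003 in Tmem173-/- cells (quartiles -0.05 to 0.08, 51.1% in the same direction, exact permutation p = 0.6 on the library means). Genes that fell in wild type cells had medians of -0.68 and -0.01 (56.5% in the same direction, exact permutation p = 0.8).

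The interferon-stimulated list was the only one of the 23 called by camera in Tmem173-/- cells, with a median of 0.17 and 0 of 35 members past the threshold, also when adjusted over the list alone (camera adjusted p = 0.0117, adjusted p = 0.983 with an estimated correlation). Fry did not call it (fry adjusted p = 0.979). Its mean log2 CPM was 3.64, 3.95 and 4.29 in controls and 4.32, 4.15 and 4.02 after cGAMP (exact permutation p = 0.4), so the libraries overlapped. Without the filter on low counts, edgeR called 10 genes higher and 13 lower. These had a median of 6869 counts over all libraries, so most were not low-count genes, and the result of 0 depends on this setting. On FPKM with a pseudocount of 1 Gm27343 was higher and on all genes Gm18258 was also lower, and with a pseudocount of 0.1 Mir6386 was higher, genes with 12, 3 and 54 counts over all libraries that were chosen after their values were seen.

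**Figure D4:**
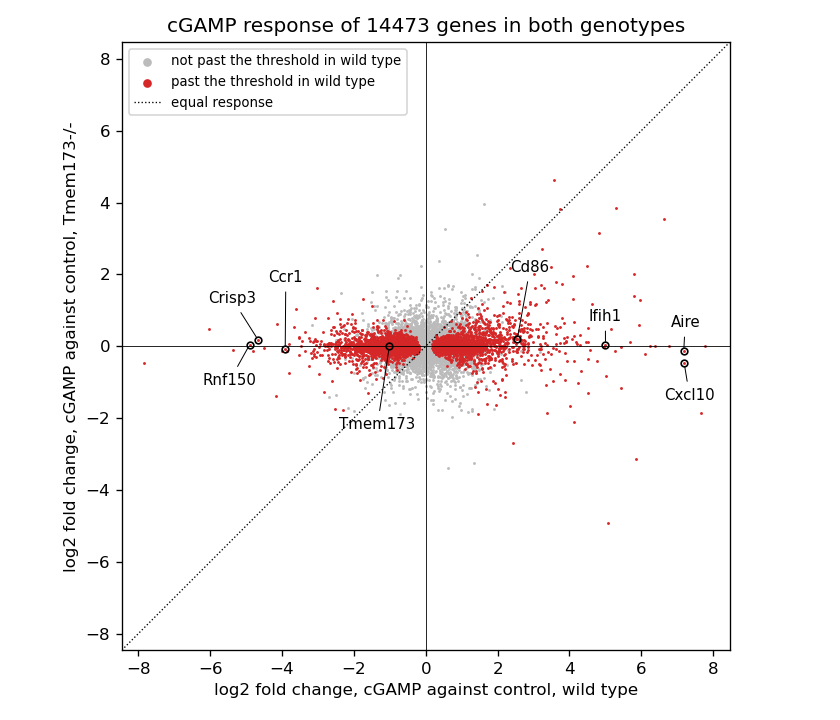
Log2 fold change after cGAMP in wild type (x axis) and Tmem173-/- cells (y axis) of 14473 genes, with genes past the threshold in wild type in red. The red points lie along the horizontal axis, with a median on the y axis of 0.003 for genes that rose and -0.01 for genes that fell in wild type cells.

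The difference of the responses asked which cGAMP effects depended on the genotype label. The response of 2532 genes was higher (less of a fall or more of a rise) and that of 2037 lower in Tmem173-/- than in wild type cells (edgeR, adjusted p under 0.05). Rnf150, Crisp3, Ccr1, Nfam1 and Pglyrp1 had the largest positive differences by the naming rule, at 4.94 (SE 0.24), 4.83 (SE 0.61), 3.83 (SE 0.25), 3.24 (SE 0.27) and 3.02 (SE 0.29). Cxcl10, Aire, Acod1, Ifi207 and Pak6 had the largest negative differences, at -7.67 (SE 1.36), -7.31 (SE 1.28), -6.60 (SE 1.04), -5.47 (SE 0.94) and -5.34 (SE 0.77). EdgeR adjusted p values of these 10 lay between 2.27e-09 and 0.00196. Tmem173 itself differed by 1.02 (SE 0.14, edgeR adjusted p = 6.43e-05). The differences of Ifna1 and Ifna4, with 4 and 0 counts over the Tmem173-/- cGAMP libraries, and of Ifi204 were not past the threshold (edgeR adjusted p = 0.896, 1 and 0.117). The Tmem173-/- controls held 0 counts of Ifna1 and 0 of Ifna4, so their Tmem173-/- response had an empty baseline. In wild type cells their counts went from 5 and 4 to 539 and 478. The tests of Ifna1 and Ifna4 therefore do not show that their rise was independent of genotype. Among genes named from the pathway lists, the difference passed for 69 of 78, against 31.6% of all tested genes. Most of these 78 were picked for a large wild type change, and the same libraries enter the difference. A high share was therefore built in.

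By list, the difference was negative for interferon-stimulated genes (median -2.54, 30 of 35 members lower, 33 when adjusted over the list alone), cytokines and chemokines (-1.32, 8 of 16 lower and 1 higher), NF-kB pathway and targets (-0.35, 13 of 23 lower and 3 higher), MHC class I presentation (-0.60, 9 of 18 lower) and cell cycle (-0.97, 16 of 25 lower and 1 higher). It was positive for MHC class II presentation (1.24, 13 of 14 higher), B cell identity and receptor signalling (0.86, 18 of 25 higher) and migration receptors (0.69, 11 of 19 higher and 2 lower). Adjusted over the list alone, 33, 10, 16, 13, 17, 14, 19 and 15 members of these lists passed, in the order given. Of these, 0, 1, 3, 0, 1, 1, 1 and 3 went against the direction of their list. The camera adjusted p values of these 8 lists lay between 4.29e-17 and 0.00147. With an estimated correlation none was called, at adjusted p = 0.323, 0.221, 0.221, 0.323, 0.508, 0.323, 0.323 and 0.221 with an estimated correlation in the order given. Fry called these 8 lists as well, and it called STING pathway components (fry adjusted p = 0.00835), B cell activation and costimulation (0.00915) and p53 targets and apoptosis (0.00401) lower and monocyte and macrophage markers (0.0335) higher. Regulatory B cell genes were not called as a list (camera adjusted p = 0.565), and their median of 0.45 and mean of -0.14 differed in sign. Of 18 members, 6 were higher, 5 were lower and 7 did not pass, and 12 passed when adjusted over the list alone. The response was lower in Tmem173-/- cells for Il10 (edgeR adjusted p = 0.0017), Lag3, Tigit, Cd274 and Ebi3, and higher for Cd24a, Cd9, Havcr1, Cd5, Cd1d1 and Tgfb1, with edgeR adjusted p values of these 11 genes between 5.9e-07 and 0.0214.

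The comparison of Tmem173-/- control with wild type control asked whether untreated B cells differed by genotype label. No gene passed the threshold with edgeR (0 higher, 0 lower, smallest adjusted p = 0.728), with 921 genes at an unadjusted p under 0.05 where chance gives 723.7. DESeq2 called Zfp341, a zinc finger transcription factor gene, higher (log2 fold change 1.45, DESeq2 adjusted p = 0.000921), and limma-voom called 0. Without the filter on low counts, edgeR called 32 genes higher and 119 lower, and 140 of these 151 were also tested with the filter. The 151 had a median of 16748 counts over all libraries. The interferon-stimulated list was lower in Tmem173-/- controls, with a median of -0.97 and 0 members called, and 22 of 35 lower when adjusted over the list alone (camera adjusted p = 1.07e-19, adjusted p = 0.708 with an estimated correlation). On the library means the difference was -0.83 (exact permutation p = 0.2). Wild type control replicate 3, the library with the highest values, carried part of this. Without it the median was -0.45 (camera adjusted p = 2.14e-16), and the unadjusted p with an estimated correlation was 0.0691, against 0.0615 with all libraries. The fitted log2 fold change was below 0, with no threshold, for 35 of 35 members without it and for 34 of 35 with all libraries. Smaller differences were called for MHC class I presentation (median -0.13, camera adjusted p = 0.00354), glycolysis (-0.16, 0.012), unfolded protein response (-0.09, 0.0173), B cell identity (0.10, 0.012) and regulatory B cell genes (0.15, 0.0173), with 0 members called in each. With an estimated correlation their adjusted p was 0.866, 0.866, 0.866, 0.866 and 0.708. Fry called neither these lists nor the interferon-stimulated list (fry adjusted p = 0.553 for the latter). Without wild type control replicate 1, edgeR called the interferon-stimulated gene Oas1a lower (log2 fold change -1.37, edgeR adjusted p = 0.0476), and without Tmem173-/- control replicate 1 it called Zfp341 higher (1.72, edgeR adjusted p = 0.0293). Without both wild type replicate 1 libraries it called Mid1, G530011O06Rik, Gm15726 and Gm47283 higher and Oas1a lower. These genes were chosen after their values were seen.

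The comparison of Tmem173-/- cGAMP with wild type cGAMP gave the genotype difference under treatment. With edgeR 3598 genes were higher and 3396 lower in Tmem173-/-, of which 1090 and 977 by at least 2-fold. Rnf150, Crisp3, Ccr1, Sema5a and Nfam1 were the named genes higher in Tmem173-/-, by 5.23, 4.95, 4.08, 3.68 and 3.40. Cxcl10 (-8.60), Aire (-7.36), Ifi204 (-7.09) and Ifna1 (-6.97) were lower, and Ifna4, with 0 counts over the Tmem173-/- cGAMP libraries and 478 over the wild type ones, was at least 166-fold lower. EdgeR adjusted p values of these 10 genes lay between 2.39e-11 and 3.62e-05. Tmem173 RNA was higher in Tmem173-/- by 0.98 (SE 0.10, edgeR adjusted p = 9.88e-07). The controls did not differ past the threshold, and the gap followed the fall of this RNA after cGAMP in wild type cells. Of the interferon-stimulated genes 35 of 35 were lower (median -3.56, camera adjusted p = 2.32e-19, adjusted p = 0.284 with an estimated correlation), and of the MHC class II genes 13 of 14 were higher (median 1.25, camera adjusted p = 1.1e-06, adjusted p = 0.284 with an estimated correlation). Without both wild type replicate 1 libraries, 3181 genes were higher and 2910 lower.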

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

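The tests of interferon-stimulated genes in wild type control replicate 3, of Tmem173 RNA and of ribosomal protein transcripts were chosen only after the result was seen.

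The cGAMP response differed between the genotype labels by a test of the difference itself. With edgeR, 2532 genes had a higher and 2037 a lower response in libraries labelled Tmem173-/-. Named genes with a lower response were Cxcl10 (-7.67), Aire (-7.31), Acod1 (-6.60), Ifi207 (-5.47), Pak6 (-5.34), Ifih1 (-4.96) and Tex15 (-4.70). Named genes with a higher response were Rnf150 (4.94), Crisp3 (4.83), Ccr1 (3.83), Nfam1 (3.24), Pglyrp1 (3.02), Anxa1 (2.87), Sema5a (2.86), Adgre1 (2.80), Bmf (2.71) and Wnt1 (2.31). List medians of the difference were -2.54 for interferon-stimulated genes, -1.32 for cytokines and chemokines, -0.354 for NF-kB pathway and targets, -0.599 for MHC class I presentation, -0.969 for cell cycle, 1.24 for MHC class II presentation, 0.865 for B cell identity and receptor signalling and 0.686 for migration receptors. Of 78 named list members, 69 passed, a share raised by picking most of them for a large wild type response.

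Other splits of the libraries were counted for each contrast. For wild type cGAMP against control, 1 of 10 splits (the real one, with 6921 genes) gave as many genes, and the highest other gave 0. For Tmem173-/- cGAMP against wild type cGAMP it was 1 of 10, with 6994 genes and a highest other of 0. For Tmem173-/- cGAMP against control it was 10 of 10, with 0 genes and a highest other of 0. For Tmem173-/- control against wild type control it was 10 of 10, with 0 genes and a highest other of 1443. That split set wild type control replicates 1 and 3 with Tmem173-/- control replicate 1 against the rest, which points to a structure among the control libraries that the genotype labels do not follow. With 10 splits no share under 0.05 can be reached. For the difference of responses, 7 of 100 splits gave as many genes (4569 in the real split, 6308 in the highest other). All 7, the real split included, divided the cGAMP libraries by genotype, and all 10 drawn splits of that kind gave at least 4169 genes, while the other 90 gave 0. The count therefore followed the division of the cGAMP libraries and does not settle whether chance can be excluded. None of these splits kept control and cGAMP libraries of the same number together by design.

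Interferon-stimulated genes stood high in wild type control replicate 3, at a mean log2 CPM of 5.56 against 4.09 and 4.73 in the other wild type controls. RNA carried over from cGAMP wells was argued against, since that library held a median of 12.1% of the cGAMP response of the induced interferon genes (95% bootstrap interval 8.32 to 15.4, 31 genes) and -2.54% of that of other induced list genes (-5.03 to 0.522, 55 genes). For other leukocytes, the highest median excess of a cell type list over the mean of the other controls was 0.421 (NK cell, SE 0.411). That of the interferon genes was 0.932 (SE 0.132). Replicate 1 itself held more neutrophil, T cell and NK cell transcripts. Over replicate 2 alone the values were 0.413 (NK cell, SE 0.406) and 0.668 (SE 0.11). The lists had 2 to 9 tested members, so a small share of other leukocytes could not be excluded. Exposure of these cells to interferon before or during culture may account for the pattern, was not tested, and no group of the design addresses it.

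Tmem173 RNA was not lower in the libraries labelled Tmem173-/-. Exchanged genotype labels among the cGAMP libraries were argued against, because the highest mean log2 CPM over the interferon-stimulated list was 4.32 in a Tmem173-/- cGAMP library and the lowest was 7.56 in a wild type cGAMP library (SD at most 0.151 in either group). Exchanged labels among the controls were argued against as the cause only for an allele that removes the transcript. They would then put a library that lacks most of it among those labelled wild type. The lowest control library held 77.9% of the Tmem173 level of the highest. With an allele that leaves the transcript in place, Tmem173 RNA cannot show an exchange, so the control labels were not checked. An allele that leaves the transcript in place cannot be told apart from other causes with counts per gene, since controls labelled Tmem173-/- held 97.2% of the wild type level. The deposited columns of these libraries carry the prefix GT, which the labels do not explain, and whether it stands for Goldenticket, a known missense allele of Tmem173, is not stated.

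Ribosomal protein transcripts, 82 genes picked after their values were seen, fell after cGAMP in wild type cells with a median log2 fold change of -0.52 (63 lower and 4 higher). In Tmem173-/- cells the median was 0.09 with 0 called, and 45 had a higher response in the difference. The median closest to 0 under 3 scalings was -0.447 (library totals, SE over genes 0.029), so the choice among them did not account for the fall. In this contrast the other scalings moved the median of all genes by only 0.018 and 0.069. An error that all 3 scalings share could not be tested, so scaling as such was not excluded. A common fall of short and abundant genes cannot be told apart, because only 22 of the 82 have neighbours of like length and abundance. Of 10000 random matched lists, 17 had a median as low with 50 neighbours per gene, 309 with 20, and 822 for the 22 genes with close neighbours, and the rules with 20 neighbours and with close neighbours were set after the result with 50 was seen.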

How the results depend on the processing

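The fits without both wild type replicate 1 libraries and the interferon list without wild type control replicate 3 were chosen only after the results were seen. Gene counts of the wild type response, the difference of responses and the genotype contrast under cGAMP stayed within 1.5 times their value under every alternative except those named here. With glmTreat against a log2 fold change of 1, a stricter question by construction, 329 genes were higher and 334 lower in wild type, 178 and 113 in the difference, and 399 and 336 between genotypes under cGAMP. On log2(FPKM + 1) of all genes, 1514 were higher in the difference, and the cause was not tested. In the Tmem173-/- response, 10 genes were higher and 13 lower without the filter on low counts, 1 higher on FPKM with either pseudocount, and 1 higher and 1 lower on FPKM + 1 of all genes. Between controls, 32 were higher and 119 lower without the filter, 1 higher with DESeq2, 1 higher on FPKM + 1 of all genes, 1 lower on FPKM + 0.1, 0 to 1 in each direction when leaving out libraries in turn, and 4 higher and 1 lower without both wild type replicate 1 libraries. The cause was not tested, and 20 of 23 and 140 of 151 of the genes called without the filter were also tested with it. With an estimated correlation, 0 of 16 pathway lists were called in wild type in place of 8, since the estimated correlation widens the test. With fry 12 were called, the 8 and regulatory B cell genes, STING pathway components, B cell activation and costimulation, and p53 targets and apoptosis. The wild type genes that rose had a median of 0.09 in Tmem173-/- when picked by glmTreat.

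For named genes, 2217 of 2270 comparisons with an alternative kept direction and side of the threshold, 37 were weaker (31 of them with glmTreat), 5 stronger and 11 reversed. The reversed values lay near 0. When leaving out libraries in turn, Il12a in wild type ranged from -0.106 to 0.21, Ctla4 from -0.743 to 0.0448 and Tmem173 between controls from -0.125 to 0.0567. Il12a was -0.0287 without both replicate 1 libraries. Tmem173 between controls was 0.0109 with library totals, 0.00421 on FPKM + 1 with and without the filter and 0.00415 on FPKM + 0.1. All these were far from the threshold, and the cause was not tested. Changing the scaling moved the median of all genes by at most 0.077, and the share of calls that were higher moved from 46.8% to 54.2% in wild type and from 55.4% to 46.8% in the difference with library totals. The number as a block changed 0 list calls in the wild type response, the only contrast in which lists were tested with it. Residuals of control and cGAMP libraries of the same number correlated at 0.083 to 0.30 against at most 0.051 for other numbers. Within each genotype, 12 of 12 libraries correlated best with their own number, a hint that equal numbers share a mouse. Likeness by number also crossed genotypes, which share no mouse. On the second principal component, number 1 libraries lay at 17.9 and 8.53 in wild type and 20.1 and 11.6 in Tmem173-/- (control, cGAMP). Number 2 libraries lay at -19.3, -13.8, -13.8 and -8.66, and number 3 libraries at 34.5, 0.381, -17.4 and -20.1. A shared mouse was thus not told apart from another effect of number. The primary fit did not use the number. With the number as a block, edgeR called 3699 genes higher and 4050 lower in the wild type response. In the Tmem173-/- response it called 0 and 0, and in the difference 3034 and 2626. In simulations at the depth of these libraries, 2-fold changes in wild type were recovered for 95.6% of genes at 5 CPM or more, 33.3% at 1 to 5 CPM and 0% below 1 CPM. Depth itself was not varied, so depth and dispersion at low counts were not separated.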

Other observations

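The values in this part were picked only after they were seen, and no explanation for them was tested. Several cytokine genes below the filter had counts mainly in wild type cGAMP libraries. Il27 had 13, 7 and 1 counts there against 0 in each wild type control, Cxcl9 had 7, 6 and 7 against 0, 1 and 0, and Cxcl11 had 3, 13 and 0 against 0 in each. Gzmb, encoding granzyme B, had 28, 2 and 1 counts after cGAMP and 2, 0 and 0 in controls, so that wild type replicate 1 carried most of them.

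Some genes differed between libraries of the same group and were alike in the control and cGAMP libraries of the same number. Ctnna1 (chromosome 18, 35118888 to 35254773), encoding alpha-catenin, which lies on the same chromosome as Tmem173, was at 68.5 CPM in both Tmem173-/- replicate 1 libraries and at 10.2 and 10.95 CPM in replicate 2 and 11.2 and 11.2 CPM in replicate 3, in control and cGAMP respectively, against 48.6 to 92.8 CPM in wild type. Zfp341 was at 13.7 and 13.1 CPM in Tmem173-/- replicate 1, at 25.4 to 29.9 CPM in Tmem173-/- replicates 2 and 3, and at 7.05 to 10.1 CPM in wild type. Ighg2c, the constant region of IgG2c, was at 42.0 and 40.2 CPM in wild type replicate 2 and at 3.43 and 6.91 CPM in wild type replicate 3.

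Gm47283 (chromosome Y, 90784738 to 90816464 in the annotation) was at 0 CPM in wild type replicates 2 and 3 under both treatments, at 2.89 and 14.1 CPM in wild type replicate 1, and at 14.03 to 27.1 CPM in the Tmem173-/- libraries. Mid1, at the end of chromosome X (169685199 to 170005736), was at 0.214 to 1.37 CPM in wild type replicates 2 and 3, at 1.75 and 4.004 CPM in wild type replicate 1, and at 5.81 to 9.44 CPM in the Tmem173-/- libraries.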
